A study of Mus musculus with 31 samples.

How the data were processed

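Hippocampal RNA of adult C57BL/6 mice of both sexes was hybridised to single-colour Agilent mouse arrays, 31 in all. Per the labels, 500 ng of total RNA was labelled with Cy3 and the scans were read with Agilent Feature Extraction 12.0; the file headers give version 12.0.0.7. The deposited scanner files hold, per spot, the authors' processed intensity, which the scanner software had background-subtracted, detrended and floored within each array, with no normalization between arrays. They also hold other columns per the file headers, flags of 0 or 1 per spot for saturation, non-uniformity and signal well above background. The deposited table of all samples holds, per probe, the mean of that processed intensity on a linear scale; each cell was checked against the scanner files and matched within the rounding of the table.

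The scanner files were used here. Control spots and spots marked as non-uniform or as population outliers were left out, spots of the same probe were averaged on the log2 scale, and the 75th percentile of each array was subtracted. The files give a transcript identifier per probe and no gene symbol, so symbols were taken from a gene table on assembly GRCm38.p6 through RefSeq identifiers; of 41174 probes, 28223 carried 1 gene symbol and 12951 carried none. The file headers name another build, so the gene table was used for names and for the order of neighbouring genes only, and no position is given. A probe was kept when it was well above background on at least 3 arrays of at least 1 group, which left 30994 probes. Each gene was represented by its probe with the highest mean signal. This gave 23024 genes, counting each transcript without a symbol as a gene of its own, of which 16066 had a name.

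Precision is limited by the number of arrays, 3 or 4 per group. Between 66.6% and 77.4% of the probes of an array were well above background, and the 75th percentile of processed intensity lay between 821 and 1159 units. Genes were sorted into terciles by their mean signal over all arrays, called dimmest, middle and brightest below.

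A model with a mean for each of the 8 groups of genotype and sex was fitted with limma 3.58.1 in R 4.3.3, and contrasts were tested with its moderated test, two-sided, with Benjamini-Hochberg adjustment within each of 16 contrasts. A gene was called at an adjusted p below 0.05. The contrasts compared each knockout with control in each sex and as the mean of both sexes, the double knockout with each single knockout, the double knockout with the sum of the single ones, each knockout effect between the sexes, and control females with control males. Known changes were added to simulated arrays, drawn with each gene's mean and spread in these data and independent noise. Of genes changed by 1 on the log2 scale, 82.1% were recovered in a comparison of GREmx1-cre with control males. The share was 77.6% for GRMREmx1-cre males and 73.1% for a difference between the sexes. The simulated arrays held no shift by slide, so these shares do not cover such a shift.

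Gene lists, 38 in all, of cell type markers and pathways were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01 between genes; the same test with an estimated correlation and fry, which does not compare a list with other genes, were run as alternatives. A list count is given over all genes tested and adjusted over the list alone. Genes are named by a rule also fixed before the data were examined: the 8 largest changes each way among called, named genes with full separation of the groups in each sex, the 5 largest each way for interaction and non-additivity contrasts, the targeted receptor genes and Emx1, and up to 4 members per list with the largest test statistic. The rule asks for a symbol in the array files, which hold none, so the symbol from the gene table stood in for it. Of the genes the rule names, those of the dimmest tercile, many of them nose receptors, are described only in part. A result for 1 further gene is not reported here. Where a gene was well above background on no array of 1 of the compared groups, its fold is a lower bound, taken after each value of that group was raised to the lowest signal well above background on its array.

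Alternatives were quantile normalization, the deposited table in place of the scanner files, no filter, a filter on all 31 arrays, the mean of all kept probes of a gene, a block for replicate number, array weights, a fit of the compared groups alone, an additional minimum fold change of 1.5, slide as a random block, the means of the 8 slides, and leaving out each array. Chosen after the data were seen were normexp background correction with offset 50 on median signals, and the brightest tercile alone. Each slide held the arrays of 1 group of 1 sex, so a group within a sex cannot be told apart from its slide. Replicate numbers follow the position on the slide and were not treated as pairs. Deviations of arrays with the same number from their group means had a median correlation of 0.037 across genes and 0.32 at the highest, with 25 of 105 such pairs over 0.1, and for 19 of 31 arrays the best partner had the same number; the number was therefore also tried as a block.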

Results

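The series measured RNA of the whole hippocampus in adult mice lacking the glucocorticoid receptor (GREmx1-cre), the mineralocorticoid receptor (MREmx1-cre) or both (GRMREmx1-cre), and in control mice carrying floxed alleles of both receptor genes (dflox control). Both receptors are transcription factors that bind corticosteroid hormones, and the Emx1-cre driver is active in excitatory neurons and astrocytes of the forebrain. There were 4 arrays for each genotype and sex, except 3 for male GRMREmx1-cre, 31 in all. Between 66.6% and 77.4% of the probes of an array were well above background, and arrays of the same group correlated at 0.984 to 0.995 across genes, which are not independent replicates; the pairs below 0.990 all held male GREmx1-cre replicate 1. Changes are given as log2 fold changes ± SE against dflox control, as the mean of the male and the female change unless a sex is named. Genes named as largest changes had no overlap between the arrays of the compared groups in either sex. Each group of a sex lay on a slide of its own, so within a sex genotype and slide cannot be told apart.

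The knocked-out genes were read first, as a check of the labels. Nr3c1, which encodes the glucocorticoid receptor, fell by 2.24 ± 0.07 in male and by 1.83 ± 0.07 in female GREmx1-cre, and by 1.64 ± 0.07 and 1.59 ± 0.07 in male and female GRMREmx1-cre. In MREmx1-cre it rose, by 0.53 ± 0.07 in males and 0.72 ± 0.07 in females. Its 4 probes moved the same way in each of these comparisons. Nr3c2, which encodes the mineralocorticoid receptor, lay in the dimmest tercile although its tested probe was well above background on all 31 arrays, and its 3 probes differed from each other. On the tested probe it rose in GREmx1-cre, by 0.42 ± 0.07 in males and 0.48 ± 0.07 in females, and dropped by 0.30 ± 0.08 and 0.37 ± 0.07 in male and female GRMREmx1-cre. In MREmx1-cre the tested probe gave -0.12 ± 0.07 in males, not called, and rose by 0.53 ± 0.07 in females, whereas another probe gave -0.78 and -0.88. Where these probes lie relative to the deleted part of Nr3c2 is not given in the sources used here, and a probe outside it checks nothing about the deletion. Emx1, the gene whose promoter drives the recombinase, fell by 0.36 ± 0.08 in GREmx1-cre, by 0.41 ± 0.08 in MREmx1-cre and by 0.49 ± 0.09 in GRMREmx1-cre. The sex labels were checked on Xist, the RNA that silences an X chromosome, which was at least 627-fold higher in control females, and on the Y-linked genes Eif2s3y, at least 124-fold lower, and Ddx3y, at least 126-fold lower. Over all groups the normalized log2 signal of the tested probe of Xist was 2.64 or more in females and -4.86 or less in males, and that of Ddx3y was 0.56 or more in males and -7.91 or less in females; the highest male value on that probe came from 1 MREmx1-cre array that stood apart from its group.

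**Figure D1:**
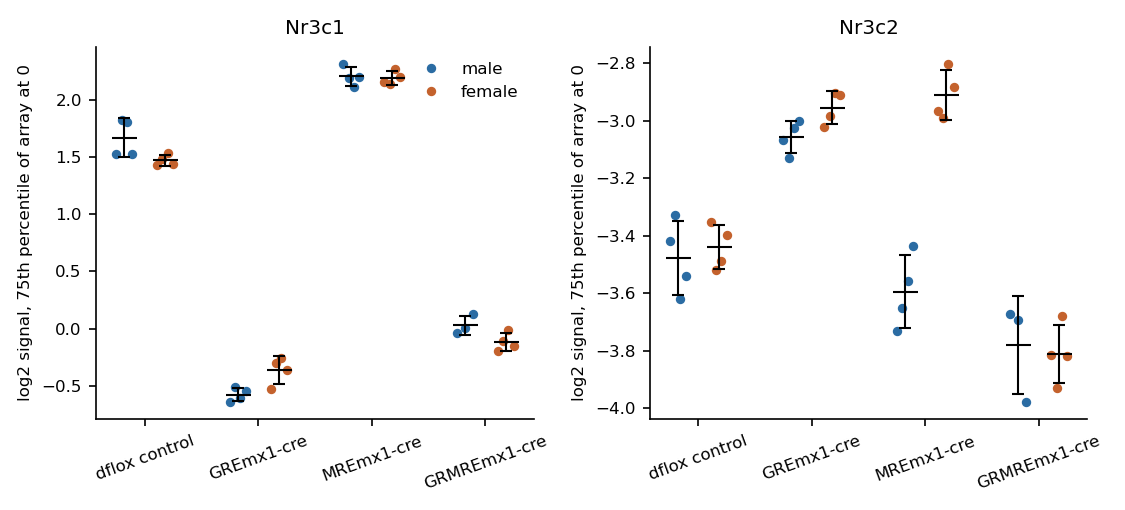
Normalized log2 signal of Nr3c1 and Nr3c2 on the tested probe, with the 75th percentile of each array at 0, per array (points) with mean and SD (black), by genotype and sex. Nr3c1 fell in GREmx1-cre and GRMREmx1-cre and rose in MREmx1-cre.

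Loss of the glucocorticoid receptor was asked about by comparing GREmx1-cre with control. Etnppl, an astrocyte enzyme that breaks down phosphoethanolamine, fell by 3.23 ± 0.25, and Cyp4f15, a fatty acid hydroxylase, fell by 1.15 ± 0.09. Glucocorticoid-responsive genes fell as a group: 8 of 30 fell and 2 rose, with 11 and 2 adjusted over the list alone. The list's adjusted p was 0.000253 at a median of -0.15, and the call was lost with adjusted p = 0.950 with an estimated correlation. Gjb6, a gap junction protein of astrocytes, fell by 0.44 ± 0.06 and Fam107a, an actin-binding protein, by 0.45 ± 0.08, while Hif3a, a hypoxia-related factor, rose by 0.45 ± 0.11. The arrays overlapped for Fkbp5 of this list. Its normalized log2 signal was -1.35 to -0.78 in male GREmx1-cre and -2.07 to -0.85 in male controls. In females it was -1.30 to -0.90 and -1.15 to -0.95.

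Several of the other named changes lay near Nr3c2 in gene order; of the 20 largest calls, 3 were among the 200 named genes nearest to it. Ocel1 fell by 2.66 ± 0.19, Klf1, a red cell transcription factor, by 1.51 ± 0.23, Il12rb1, a cytokine receptor chain, by 1.30 ± 0.11, and Slc5a5, the iodide transporter, rose by 1.58 ± 0.13; all 4 are among the 100 named genes on either side of Nr3c2. Lpl, which releases fatty acids from lipoproteins, fell by 1.48 ± 0.12, Ccl17, a chemokine, by 1.39 ± 0.11, and Crnde, a long non-coding RNA, rose by 2.09 ± 0.21; these lie a little further out, 117, 136 and 111 genes away. Mt1 of the glucocorticoid-responsive list, a metal-binding protein 125 genes away, fell by 0.25 ± 0.05. Of the 200 named genes nearest to Nr3c2, 80 were called, 40%, against 1108 of the other 15865, 6.98%. In GRMREmx1-cre, Ocel1 was at 0.13 ± 0.19, Klf1 at -0.26 ± 0.23, Ccl17 at -0.13 ± 0.12 and Slc5a5 at -0.12 ± 0.13, none of them called, whereas Il12rb1 fell by 0.45 ± 0.12, Lpl fell by 0.49 ± 0.13 and Crnde rose by 0.90 ± 0.22, all called. Of the 80 called neighbours 14 were called in the same direction in GRMREmx1-cre and 11 in the opposite one. Away from Nr3c2, Etnppl fell by 3.85 ± 0.26 and Cyp4f15 fell by 1.55 ± 0.09.

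**Figure D2:**
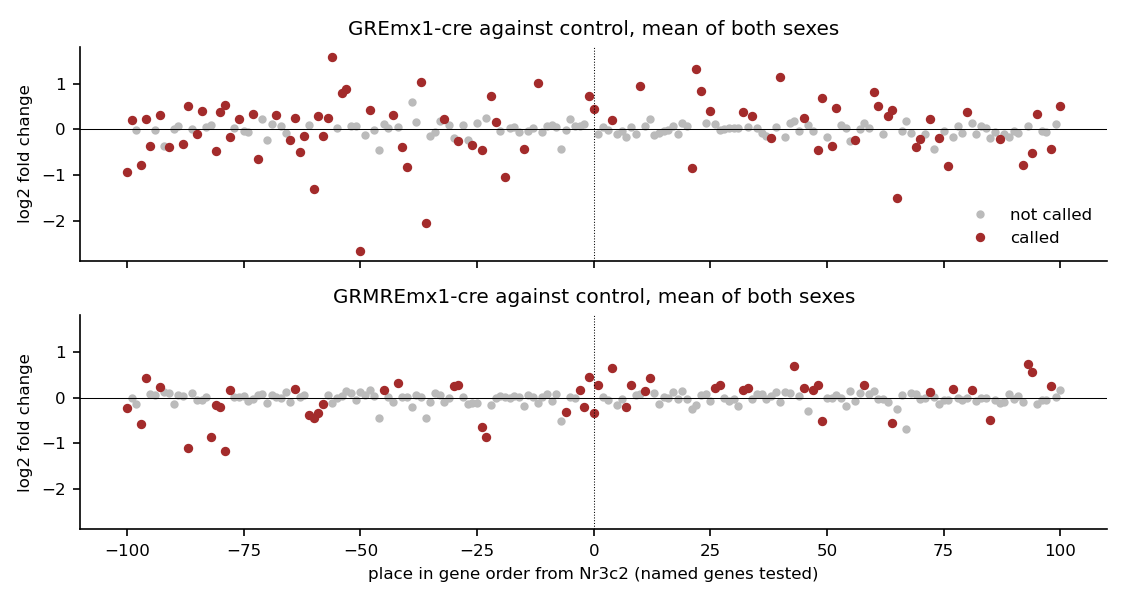
Log2 fold change against control, mean of both sexes, of the named genes nearest to Nr3c2 by their place in gene order, in GREmx1-cre (top) and GRMREmx1-cre (bottom), with called genes in red. In GREmx1-cre 80 of the 200 neighbours were called, 43 higher and 37 lower.

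Microglia markers rose in GREmx1-cre in 6 of 20 members and fell in 1, with 9 and 2 adjusted over the list alone. C1qa, C1qb and C1qc, which encode the chains of complement C1q, rose by 0.35 ± 0.06, 0.31 ± 0.07 and 0.31 ± 0.05. The list's adjusted p was 0.0264 at a median of 0.10, but adjusted p = 0.950 with an estimated correlation. Interferon-response genes rose as a group at an adjusted p of 0.0251 and a median of 0.18, lost at adjusted p = 0.950 with an estimated correlation; 1 of 16 rose, and 6 adjusted over the list alone, with Ifit3, an antiviral protein, up by 0.64 ± 0.09. Myelinating oligodendrocyte markers rose in 3 of 18 and fell in 1, and 6 and 1 adjusted over the list alone, at an adjusted p of 0.0360 and a median of 0.12, lost at adjusted p = 0.950 with an estimated correlation. Immediate early genes fell at an adjusted p of 0.00726 and a median of -0.18, with 2 of 21 falling both over all genes and adjusted over the list alone, and adjusted p = 0.950 with an estimated correlation. Astrocyte markers did not move as a group, at an adjusted p of 0.874 and with a positive median of 0.03 against a downward test. Aqp4, the water channel of astrocyte end-feet, rose by 0.47 ± 0.06 and Aldoc, a glycolytic enzyme, fell by 0.29 ± 0.05. S100a10, an S100 family protein of reactive astrocytes, rose by 0.71 ± 0.06.

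The comparison called 1763 genes of 23024, 1421 higher and 342 lower, and 1031 of them were in the dimmest tercile, 919 higher and 112 lower, against 235 in the brightest, 129 and 106; the brightest tercile alone gave 90 and 72. With slide as a random block 402 were called, and the calls of Emx1, C1qb, Mt1 and Hif3a were lost; with the 8 slide means limma called 0, and 947 passed at an unadjusted p under 0.05; with the mean of all kept probes Hif3a turned to -0.30. In males 1290 and in females 1751 genes were called, and the male count was 329 with only the compared groups fitted and 618 without male control 3.

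Loss of the mineralocorticoid receptor was read from MREmx1-cre against control, where markers of several hippocampal neurons differed. Aldh1a3, which makes retinoic acid, rose by 3.04 ± 0.13, and the keratins Krt10 and Krt12 rose by 2.11 ± 0.09 and 1.89 ± 0.11. Dsp, a desmosome protein marking dentate granule cells, fell by 2.35 ± 0.10, Spink8, a protease inhibitor, by 2.08 ± 0.15, Olfml2b by 2.29 ± 0.14, Tmprss6, a membrane protease, by 2.32 ± 0.22, Fam160a1 by 1.94 ± 0.18 and Grem1, an inhibitor of bone morphogenetic proteins, by 2.86 ± 0.31. Rtl3 was at least 1.97-fold lower in males and at least 2.34-fold lower in females. Glucocorticoid-responsive genes fell in 15 of 30 members and rose in 1, with 17 and 1 adjusted over the list alone. Fkbp5, a chaperone of both receptors, fell by 1.49 ± 0.13, Cebpd, a transcription factor, by 0.84 ± 0.12, Errfi1, an inhibitor of the EGF receptor, by 0.56 ± 0.06 and Rhob, a small GTPase, by 0.45 ± 0.06. The list's adjusted p was 2.65e-09 at a median of -0.20, and adjusted p = 0.0612 with an estimated correlation.

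Markers of the CA2 field fell in 7 of 14 members and rose in 1, and 9 and 1 adjusted over the list alone. Amigo2, an adhesion protein, fell by 1.36 ± 0.15, Cacng5, an auxiliary AMPA receptor subunit, by 1.23 ± 0.17, Necab2, a calcium-binding protein, by 1.12 ± 0.09, and Pcp4, a calmodulin regulator, by 0.49 ± 0.05. The list's adjusted p was 1.89e-06 at a median of -0.24, and 0.000419 with an estimated correlation. CA3 markers fell in 6 of 13 and rose in 1, and 8 and 1 adjusted over the list alone, at an adjusted p of 2.5e-05 and a median of -0.31, and 0.0472 with an estimated correlation. Mas1, a peptide receptor, fell by 0.51 ± 0.06, Spock1, a proteoglycan, by 0.45 ± 0.06 and Grik4, a kainate receptor subunit, by 0.34 ± 0.05. Dentate granule cell markers fell in 8 of 18 and rose in 2, and 9 and 2 adjusted over the list alone; Calb1, the calcium buffer calbindin, fell by 1.39 ± 0.06, whereas C1ql3, a synaptic organizer, rose by 0.22 ± 0.05. Their adjusted p was 8.91e-07 at a median of -0.17, and adjusted p = 0.0612 with an estimated correlation. CA1 markers did not move as a group, at an adjusted p of 0.646 and a median of 0.03, with 4 of 12 rising and 1 falling, the same numbers adjusted over the list alone. Wfs1, an endoplasmic reticulum protein, and Lmo4, a transcriptional adaptor, rose by 0.69 ± 0.06 and 0.50 ± 0.04, and Lefty1, a TGF-beta family ligand, fell by 0.91 ± 0.13. Adult neurogenesis genes gave an adjusted p of 0.919 and a median of 0.00, with 6 of 15 rising and 3 falling, the same adjusted over the list alone.

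Microglia markers rose in 14 of 20 members, and 19 adjusted over the list alone, at an adjusted p of 1.04e-05 and a median of 0.19, but adjusted p = 0.273 with an estimated correlation; Fcrls, a microglial receptor, rose by 0.33 ± 0.06 and Gpr34, a lysophospholipid receptor, by 0.31 ± 0.06. Immediate early genes fell in 7 of 21, and 11 adjusted over the list alone, at an adjusted p of 4.18e-05 and a median of -0.24, lost at adjusted p = 0.472 with an estimated correlation. Jun and Gadd45b, which respond to neuronal activity and stress, fell by 0.41 ± 0.06 and 0.45 ± 0.07. Oligodendrocyte precursor markers rose in 4 of 11, the same adjusted over the list alone, at an adjusted p of 0.0440 and a median of 0.13, lost at adjusted p = 0.472 with an estimated correlation. Oxidative phosphorylation genes fell at an adjusted p of 0.00164 and a median of -0.06, with 3 of 20 falling, and 2 adjusted over the list alone, and adjusted p = 0.764 with an estimated correlation. Choroid plexus markers, which report neighbouring tissue in a dissection, varied widely within groups and 0 of 15 were called by limma, at a median of -0.64.

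The comparison called 5050 genes, 3442 higher and 1608 lower, and 962 and 859 in the brightest tercile alone, with 2176 in males and 3648 in females. With slide as a random block 2032 were called and the call of C1ql3 was lost, and with the 8 slide means 34 were called. With only the compared groups fitted the male count was 726.

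Loss of both receptors was read from GRMREmx1-cre against control. Etnppl fell by 3.85 ± 0.26, Spink8 fell by 3.65 ± 0.15, Dsp fell by 3.10 ± 0.10, Rasd1, a dexamethasone-induced GTPase, fell by 3.08 ± 0.20 and Olfml2b fell by 2.87 ± 0.14. Aldh1a3 rose by 3.67 ± 0.14, Cxcl5, a neutrophil-attracting chemokine, by 3.55 ± 0.23, Krt12 by 2.29 ± 0.12, Krt10 by 2.27 ± 0.10, Wdr95 by 2.07 ± 0.08 and Hspb3, a small heat shock protein, by 1.89 ± 0.11. Grem1 was at least 8.73-fold lower in males. Glucocorticoid-responsive genes fell in 21 of 30 and rose in 1, and 21 and 3 adjusted over the list alone, at an adjusted p of 5.2e-12 and a median of -0.44, and 0.0258 with an estimated correlation. Fkbp5 fell by 1.93 ± 0.14, Cebpd by 1.44 ± 0.12 and Bcl6, a transcriptional repressor, by 1.03 ± 0.09.

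Microglia markers rose in all 20 measured members, also adjusted over the list alone, at an adjusted p of 4.49e-18 and a median of 0.41, and 0.00793 with an estimated correlation. Fcrls rose by 0.59 ± 0.07, C1qc by 0.51 ± 0.05, Aif1, a microglial calcium-binding protein, by 0.51 ± 0.06 and Trem2, a lipid-sensing receptor, by 0.48 ± 0.05. Activated microglia genes rose in 7 of 16 and fell in 1, and 11 and 1 adjusted over the list alone, at an adjusted p of 0.00118 and a median of 0.19, lost at adjusted p = 0.313 with an estimated correlation; Itgax, an integrin, rose by 1.61 ± 0.25 and Ccl4, a chemokine, by 0.97 ± 0.16. Oligodendrocyte precursor markers rose in 7 of 11, and 8 adjusted over the list alone, at an adjusted p of 0.000189 and a median of 0.16, but adjusted p = 0.0686 with an estimated correlation. C1ql1, a secreted synaptic protein, and Gpr17, a receptor of differentiating precursors, rose by 0.44 ± 0.05 and 0.43 ± 0.07.

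CA2 markers fell in 7 of 14 and rose in 1, the same adjusted over the list alone, at an adjusted p of 0.000674 and a median of -0.27, and 0.00793 with an estimated correlation. CA3 markers fell in 8 of 13, and 10 adjusted over the list alone, at an adjusted p of 0.000115 and a median of -0.25, and 0.0307 with an estimated correlation. Dentate granule cell markers fell in 12 of 18 and rose in 1, the same adjusted over the list alone, at an adjusted p of 8.02e-09 and a median of -0.41, and 0.0258 with an estimated correlation; Calb1 fell by 1.66 ± 0.07. CA1 markers gave an adjusted p of 0.921, a negative median of -0.04 and an upward test. Among astrocyte markers Aqp4 rose by 0.83 ± 0.06 and Gja1 by 0.36 ± 0.04, whereas Gjb6 fell by 0.63 ± 0.06 and Aldoc by 0.48 ± 0.05; the list gave an adjusted p of 0.202 at a median of 0.06. Cd44, an adhesion receptor of reactive astrocytes, rose by 1.10 ± 0.15, S100a10 by 1.09 ± 0.07 and Osmr, the oncostatin M receptor, by 0.79 ± 0.06, and that list gave an adjusted p of 0.202 at a median of 0.07. Choroid plexus markers had a median of -0.83, with 0 of 15 called by limma.

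**Figure D3:**
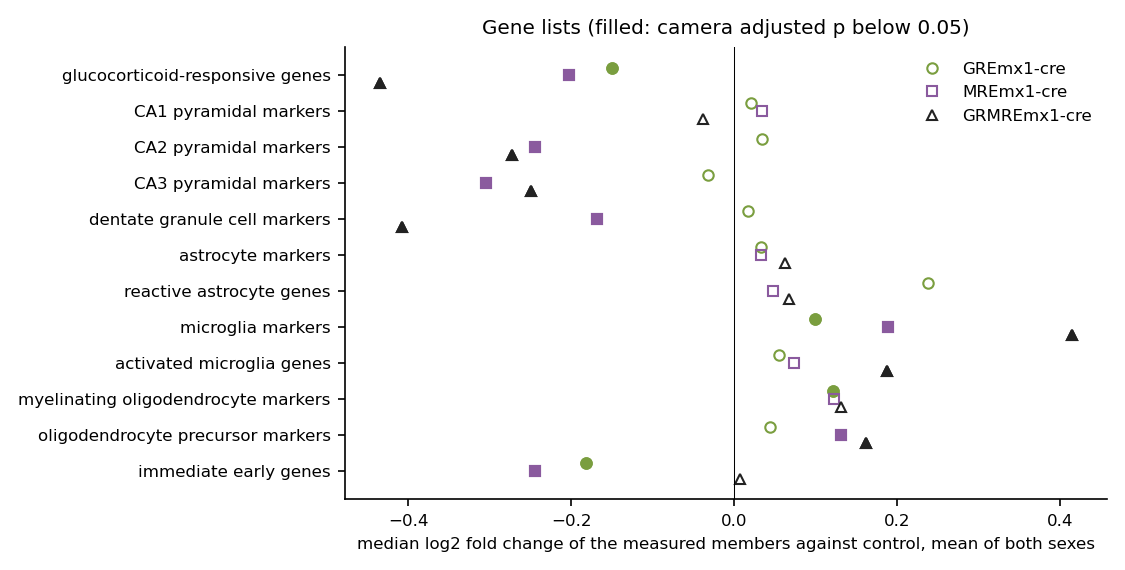
Median log2 fold change against control, mean of both sexes, of the measured members of 12 gene lists (rows) in GREmx1-cre (circles), MREmx1-cre (squares) and GRMREmx1-cre (triangles), filled where camera's adjusted p was below 0.05. Microglia markers had medians of 0.10, 0.19 and 0.41.

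The comparison called 5401 genes, 2794 higher and 2607 lower, and 1276 and 1194 in the brightest tercile alone and 3084 and 1890 with normexp. The split was opposite in the sexes, with 4399 called in males, 3039 higher and 1360 lower, and 5828 in females, 1956 higher and 3872 lower. The brightest tercile alone turned it round, with 691 higher and 833 lower in males and 979 and 730 in females. Quantile normalization gave 2298 higher and 1482 lower in males and 2678 and 2837 in females. Normexp gave 2709 and 1293 in males and 2127 and 2231 in females. With slide as a random block 2637 were called, and with the 8 slide means 384; without male array 2 of GRMREmx1-cre the male count was 2885. The shift of dim genes differed between the sexes: the 426 nose receptor genes, which mark the dimmest signals, had a median of 0.62 in males and -1.11 in females.

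What loss of the mineralocorticoid receptor added where the glucocorticoid receptor was already lost was read from GRMREmx1-cre against GREmx1-cre. Aldh1a3 was higher by 3.78 ± 0.14, Krt12 by 2.28 ± 0.12, Wdr95 by 2.16 ± 0.08, Hspb3 by 2.11 ± 0.11 and Dach1, a transcription factor, by 1.86 ± 0.09. Spink8 fell by 3.75 ± 0.15, Dsp by 3.08 ± 0.10 and Rasd1 by 2.98 ± 0.20. Ocel1, near Nr3c2, was higher by 2.79 ± 0.19. Dentate granule cell markers fell in 13 of 18 and rose in 2, the same adjusted over the list alone, at an adjusted p of 1.51e-07 and a median of -0.45, and 0.0476 with an estimated correlation. CA2 markers fell in 9 of 14 and rose in 1, the same adjusted over the list alone, at an adjusted p of 0.00065 and a median of -0.29, and 0.0138 with an estimated correlation. Microglia markers rose in 16 of 20, and 18 adjusted over the list alone, at an adjusted p of 6.78e-11 and a median of 0.33, and 0.0476 with an estimated correlation. Glucocorticoid-responsive genes fell in 16 of 30 and rose in 3, and 17 and 3 adjusted over the list alone, at an adjusted p of 8.15e-05 and a median of -0.29, lost at adjusted p = 0.290 with an estimated correlation. The comparison called 6455 genes, 2814 higher and 3641 lower; quantile normalization gave 3509 higher and 3231 lower, and the brightest tercile alone 1128 and 1189. A random block for slide left 3330 calls and the 8 slide means 352.

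What loss of the glucocorticoid receptor added where the mineralocorticoid receptor was already lost was read from GRMREmx1-cre against MREmx1-cre. Cxcl5 was higher by 3.28 ± 0.23, Klk6, a protease of oligodendrocytes, by 1.61 ± 0.16, Chrdl1, an astrocyte-secreted inhibitor of bone morphogenetic proteins, by 1.57 ± 0.07, S100a10 by 1.19 ± 0.07 and Apln, a peptide ligand, by 1.13 ± 0.08. Etnppl fell by 3.06 ± 0.26 and Nr3c1 by 2.24 ± 0.05. Microglia markers rose in 12 of 20, and 13 adjusted over the list alone, at an adjusted p of 1.87e-11 and a median of 0.22, lost at adjusted p = 0.117 with an estimated correlation. Immediate early genes rose in 5 of 21, and 8 adjusted over the list alone, at an adjusted p of 7.81e-05 and a median of 0.25, lost at adjusted p = 0.545 with an estimated correlation. Glucocorticoid-responsive genes fell in 14 of 30 and rose in 1, and 16 and 2 adjusted over the list alone, at an adjusted p of 0.00817 and a median of -0.17, lost at adjusted p = 0.645 with an estimated correlation. The comparison called 3640 genes, 1079 higher and 2561 lower; quantile normalization gave 1613 and 2004, and the brightest tercile alone 460 and 445. With slide as a random block 1150 were called, and with the 8 slide means limma called 0, with 1864 at an unadjusted p under 0.05.

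Whether the double knockout effect equals the sum of the single ones was tested by their difference. Ocel1 exceeded the sum by 2.77 ± 0.27, Klf1 by 1.44 ± 0.33 and Ccl17 by 1.43 ± 0.16, all 3 near Nr3c2, and Cxcl5 by 1.82 ± 0.32. Immediate early genes lay above the sum in 6 of 21 members, and 14 adjusted over the list alone, at an adjusted p of 2.06e-06 and a median of 0.43, lost at adjusted p = 0.688 with an estimated correlation. Egr2 exceeded it by 1.27 ± 0.31, Fos by 1.14 ± 0.31, Egr1, which lies near Nr3c1, by 0.54 ± 0.14 and Gadd45b by 0.43 ± 0.10, and these 4 calls were lost with slide as a random block. The test called 2418 genes, 385 higher and 2033 lower, 1514 of them in the dimmest tercile; quantile normalization gave 844 higher and 1717 lower, and the brightest tercile alone 75 and 69. With slide as a random block 1125 were called, and with the 8 slide means limma called 0, with 1351 at an unadjusted p under 0.05.

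Sex in the controls was compared as the background of sex-dependent effects. Besides the Y-linked and X-linked genes, Tsix, the antisense partner of Xist, was higher in females by 2.89 ± 0.16, Cxcl5 fell by 2.17 ± 0.31 and Sod3, an extracellular antioxidant enzyme, by 1.29 ± 0.29 from males to females. Of 7 measured X-inactivation escape genes 7 were higher in females, and of 5 Y-linked genes 4 were lower, the same adjusted over the list alone, with medians of 0.40 and -4.87 and adjusted p of 9.12e-07 for both with an estimated correlation. The Y-linked median rests on fitted changes without the lower bounds used for Eif2s3y and Ddx3y, so its size is not exact. Immediate early genes were lower in 4 of 21, and 6 adjusted over the list alone, at an adjusted p of 3.4e-07 and a median of -0.34, lost at adjusted p = 0.385 with an estimated correlation. Choroid plexus markers had a median of -1.23 with 0 of 15 called by limma, at an adjusted p of 0.00398 and adjusted p = 0.813 with an estimated correlation. The comparison called 1838 genes, 1624 higher in females and 214 lower, with 1232 in the dimmest tercile and 135 in the brightest. Quantile normalization gave 805 higher and 440 lower, normexp 992 and 403, and the brightest tercile alone 29 and 16.

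Sex-dependent knockout effects, the question in the series title, were tested as the female change minus the male change. Cxcl5 had a larger female change, by 2.18 ± 0.44 in GREmx1-cre and by 1.93 ± 0.46 in GRMREmx1-cre: it rose by 2.54 ± 0.31 in female GREmx1-cre, was at 0.36 ± 0.31 in males, and rose by 4.51 ± 0.31 and 2.58 ± 0.34 in female and male GRMREmx1-cre. Its level hardly differed between the sexes of GREmx1-cre, at a normalized log2 signal of -2.50 in males and -2.49 in females, or of GRMREmx1-cre, at -0.28 and -0.52, whereas controls were at -2.86 and -5.03, so the difference in effect follows the difference between control sexes. Ccdc153, an ependymal gene, differed by 1.51 ± 0.40 and Sod3 by 1.35 ± 0.42 in GRMREmx1-cre; Sod3 likewise was at -4.83 and -4.76 in male and female GRMREmx1-cre and at -3.83 and -5.12 in controls. The calls numbered 562 in GREmx1-cre, 847 in MREmx1-cre and 2501 in GRMREmx1-cre, of which 95, 31 and 124 lay in the brightest tercile and 288, 655 and 1895 in the dimmest. The count for GREmx1-cre was 308 without male control 3, 345 without a filter and 861 with a replicate block, that for MREmx1-cre 386 with probes well above background on all 31 arrays, and that for GRMREmx1-cre 1550 with normexp and 1185 with those probes. Within the brightest tercile alone, adjusted among those genes, 69, 0 and 11 were called by limma; beside the count of 0, 757 of them passed at an unadjusted p under 0.05. Myelinating oligodendrocyte markers gave an adjusted p of 6.49e-06 for GRMREmx1-cre at a median of 0.30, with 1 of 18 higher, and 4 adjusted over the list alone, lost at adjusted p = 0.937 with an estimated correlation.

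**Figure D4:**
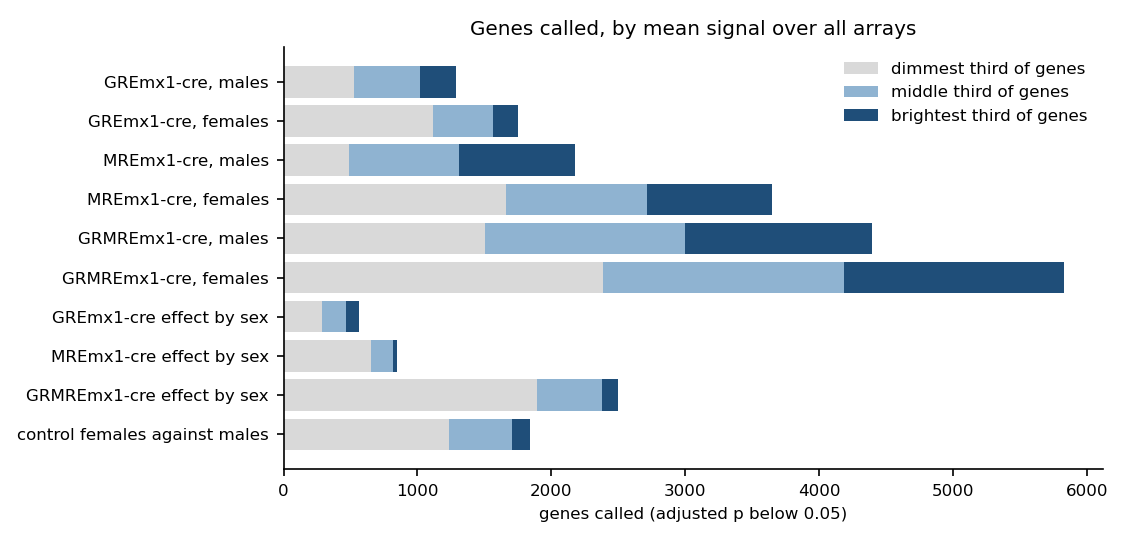
Number of genes called at an adjusted p below 0.05 per comparison (bars), divided by tercile of mean signal over all arrays. Of the 2501 sex-dependent calls of GRMREmx1-cre, 1895 lay in the dimmest tercile and 124 in the brightest.

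Male and female changes share no array. In the brightest tercile they correlated across genes at 0.81 in GRMREmx1-cre, 0.70 in MREmx1-cre and 0.17 in GREmx1-cre, in the dimmest tercile at -0.30, 0.27 and 0.22, and over all genes at -0.16, 0.39 and 0.20, with 1008, 28 and 19 genes called in opposite directions. In that brightest tercile 417 genes were higher and 439 lower in both sexes of GRMREmx1-cre, where independent lists would share 78.7 and 68.9, and 7 were called in opposite directions. In MREmx1-cre 190 were higher and 234 lower in both sexes against 24.9 and 26.2, with 0 in opposite directions by limma. In GREmx1-cre 30 were higher and 24 lower against 1.68 and 1.59, with 2 opposite. Neighbours of Nr3c2 were not left out of these numbers. Among bright ones Ocel1 changed by -2.39 in male and -2.93 in female GREmx1-cre, and Map1s by 0.77 and 0.83. Agreement between the sexes of GREmx1-cre thus does not by itself show an effect of the receptor.

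**Figure D5:**
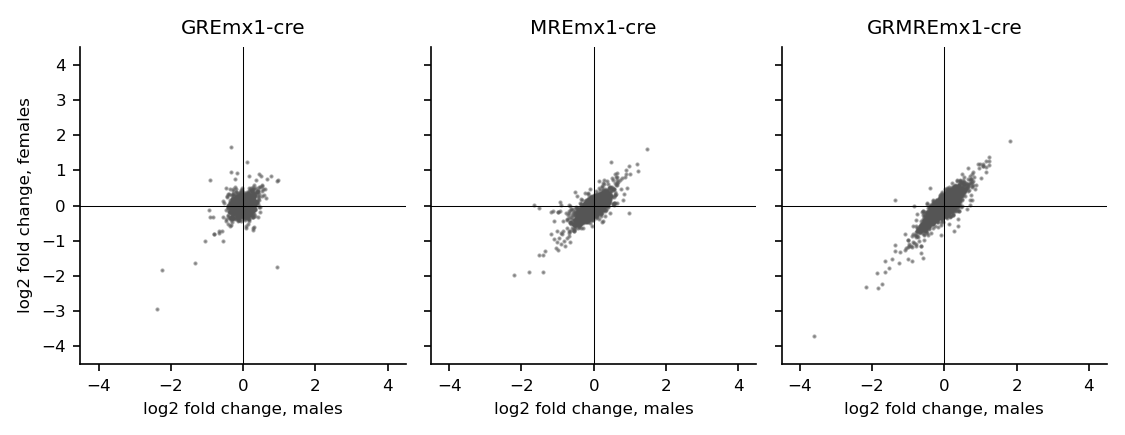
Log2 fold change against control in females (vertical) against males (horizontal) for genes of the brightest tercile (points), for GREmx1-cre, MREmx1-cre and GRMREmx1-cre. The correlations across genes were 0.17, 0.70 and 0.81.

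Within a sex the genotypes share their 4 controls, which alone makes changes correlate. The correlations and covariances below are over all genes, and the simulated groups held no shift by slide. Such a shift of dim genes can raise or lower them. The 426 nose receptor genes had medians of 0.50 in female MREmx1-cre and -1.11 in female GRMREmx1-cre. These correlations therefore cannot tell likeness of the knockout effects from slide. Male MREmx1-cre and GRMREmx1-cre correlated at 0.65 across genes, against 0.46 for simulated groups without change, and at 0.41 with the controls split; their covariance was 0.0778 against a simulated 0.0216. Female MREmx1-cre and GRMREmx1-cre correlated at 0.13 against a simulated 0.50, and at 0.04 with split controls, with covariances of 0.0266 and 0.0220. Male GREmx1-cre and GRMREmx1-cre correlated at 0.46 against 0.47, and at 0.24 with split controls, with covariances of 0.0540 and 0.0219, and female ones at 0.23 against 0.50, and 0.11, with 0.0392 and 0.0219. Male GREmx1-cre and MREmx1-cre correlated at 0.42 against 0.50, and at 0.15 with split controls, with covariances of 0.0362 and 0.0218, and female ones at 0.61 against 0.50, and 0.44, with 0.0905 and 0.0217. In the brightest tercile MREmx1-cre and GRMREmx1-cre shared 282 higher and 292 lower genes in males, where independent lists would share 42.2 and 35.9, and 260 and 334 in females, against 46.5 and 50.4. GREmx1-cre and GRMREmx1-cre shared 31 and 39 in males against 9.59 and 15.4, and 65 and 24 in females against 13.8 and 7.08, and GREmx1-cre and MREmx1-cre shared 15 and 17 in males against 7.58 and 7.38, and 19 and 13 in females against 5.52 and 5.64. Shared controls add to these numbers. Dividing the controls does not remove what their slide adds, since the 4 controls of a sex lay on 1 slide. With the controls divided between the comparisons, a mean over 6 divisions, MREmx1-cre and GRMREmx1-cre shared 112 and 155 in males against 12.5 and 13.8. In females they shared 122 and 192 against 16.8 and 20.9. GREmx1-cre and GRMREmx1-cre then shared 8.5 and 10.5 in males against 2.26 and 4.05, and 25.7 and 7.67 in females against 4.7 and 2.59, and GREmx1-cre and MREmx1-cre 1.17 and 2.67 in males against 1.21 and 1.75, and 3.5 and 2.17 in females against 1.58 and 1.73.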

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

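The test of dim signals below, and Xist, Ddx3y, spots left out and correlation within the group as measures for single arrays, were chosen only after the result was seen. In 2 of 84 groups of 4 arrays an array stood apart, tested for 6 genes, nose receptor and choroid plexus genes, array scale, share of probes above background, spots left out and correlation within the group, where chance alone would mark 5% of groups. In male GREmx1-cre replicate 1, 188 spots were left out against 58 to 74 in the others of its group; it also had the lowest array weight, 0.481, and correlated with them at 0.984 to 0.986, which did not pass the rule, and without it the sex difference in GREmx1-cre gave 362 calls. In male MREmx1-cre replicate 4 Xist was at -4.86 against -8.55 to -8.40 in the others of its group. On 2 other probes of Xist replicate 3 was higher, at -3.52 and -3.57, and Ddx3y of replicate 4 was 0.78; the cause was not tested. What marked the other results of this part was a tested difference between the sexes in the effect of a knockout.

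The knockout effect differed between the sexes for 562 genes in GREmx1-cre, 847 in MREmx1-cre and 2501 in GRMREmx1-cre. In GREmx1-cre, the female change minus the male change was 2.18 for Cxcl5 and -7.89 for Ccl21a, a chemokine. It was 0.41 for Nr3c1, which fell in both sexes and less in females on its tested probe. Its other probes gave -1.896, -1.965 and -1.638 in males and -1.369, -1.709 and -1.731 in females, so the last went the other way. In MREmx1-cre the difference was 2.50 for Trat1, a T cell adaptor, -2.01 for Mup4, a urinary protein, and 0.65 for Nr3c2 on its tested probe, whereas another probe of it gave -0.78 in males and -0.88 in females. In GRMREmx1-cre it was 1.93 for Cxcl5, 1.51 for Ccdc153 and 1.35 for Sod3. From control males to control females Cxcl5 fell by 2.17 and Sod3 fell by 1.29, so these differences in effect follow the control levels. The calls of Ccl21a and Nr3c1 in GREmx1-cre and of Sod3 in GRMREmx1-cre were lost when single arrays were left out.

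Of the genes of the brightest tercile 1.09% were called for such a difference, and of the dimmest 12.3%, a mean over the 3 genotypes. The ratio of 0.0881 is consistent with a shift of dim signals that follows the slide, since every group of a sex had a slide of its own. Scaling each array by a single percentile stays open: with quantile normalization 2688 of the 3910 calls were kept in the same direction, a share of 0.687, made up of 479 of 562 in GREmx1-cre, 778 of 847 in MREmx1-cre and 1431 of 2501 in GRMREmx1-cre. A real difference between the sexes in dim genes stays open and was not tested apart from slide, because the design holds no slide with more than 1 group.

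Other ways of exchanging the sex labels within each genotype were counted for these 3 results. For GREmx1-cre 3 of 100 gave as many calls, the real one included. The highest of the others was 758 against the real 562, so chance is not firmly excluded. For MREmx1-cre 5 of 100 did, with 1228 against 847, so chance cannot be excluded. For GRMREmx1-cre 1 of 100 did, the real one, with 1824 against 2501, which argues against chance but not against the slide. Each group of a sex had its own slide, so a shift by slide would also favour the real labels. These counts therefore cannot tell sex from slide.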

How the results depend on the processing

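Normexp on median signals and the brightest tercile alone were chosen only after the data were seen; normexp on mean signals was not run, since the files hold no such column. Of 538 recomputed values of the counts, the receptor genes and the numbers of lists, 416 kept direction and side of the threshold or stayed within 1.5 times, 11 lost their call, 3 reversed and 108 moved. Of 4742 recomputed values of named genes 4522 kept direction and side of the threshold, 216 lost the call, 2 reversed and 2 moved without a call. Most of these values came from leaving out single arrays, where 2868 kept it and 54 lost it. With the 8 slide means 50 kept it and 115 lost it. Of 318 values for lists 203 kept it and 115 lost it. With an estimated correlation 22 list values kept it and 84 lost it. The cause was not tested unless given. Low signal over background limits the dim genes.

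Counts are given below in the order males, females, mean of both sexes. In the brightest tercile alone, where fewer genes are tested, GREmx1-cre gave 248, 126 and 162, MREmx1-cre 1080, 938 and 1821, and GRMREmx1-cre 1524, 1709 and 2470. The sex differences of these effects gave 69, 0 (limma, 757 unadjusted) and 11, control females against males 45, GRMREmx1-cre against GREmx1-cre 2317 and against MREmx1-cre 905, and non-additivity 144. With an additional minimum fold change of 1.5, GREmx1-cre gave 374, 1058 and 721, MREmx1-cre 526, 1674 and 1251, GRMREmx1-cre 1614, 2527 and 793, the sex difference in GREmx1-cre 332, control sex 1136, GRMREmx1-cre against GREmx1-cre 1695 and against MREmx1-cre 1244, and non-additivity 1584.

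With slide as a random block the means of both sexes gave 402 for GREmx1-cre, 2032 for MREmx1-cre, 2637 for GRMREmx1-cre, 3330 and 1150 for GRMREmx1-cre against GREmx1-cre and MREmx1-cre, and 1125 for non-additivity, at a correlation within slide of 0.180. With the 8 slide means, fewer samples, they gave 0, 34, 384, 352, 0 and 0 by limma, the counts of 0 with 947, 1864 and 1351 at an unadjusted p under 0.05. With probes well above background on all 31 arrays GREmx1-cre gave 999 in females and 1002 over both sexes, the sex differences 386 in MREmx1-cre and 1185 in GRMREmx1-cre, control sex 1061 and non-additivity 1276. With only the compared groups in the fit male GREmx1-cre gave 329 and male MREmx1-cre 726. The sex difference in GREmx1-cre was 345 without a filter and 861 with a replicate block, and that in GRMREmx1-cre was 1550 with normexp.

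For Nr3c2, normexp gave -0.16 and -0.12 in male and female GRMREmx1-cre. Another probe of Nr3c2 gave 0.51 and -0.29 in male and female GREmx1-cre, -0.88 in female MREmx1-cre, and -0.32 and -0.69 in male and female GRMREmx1-cre, reversed in female GREmx1-cre and female MREmx1-cre. A further probe gave 0.16 and 0.33, 0.15, and -0.29 and 0.16 for the same groups, reversed in female GRMREmx1-cre. A further probe of Nr3c1 gave 0.66 and 0.64 in male and female MREmx1-cre, no longer called. With the mean of all kept probes Hif3a in GREmx1-cre reversed to -0.30 and Cck in MREmx1-cre, called at -0.25, to 0.0066.

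Numbers of lists with an estimated correlation were 0, 0 and 0 for GREmx1-cre, 4, 1 and 2 for MREmx1-cre, 4 and 1 for males and females of GRMREmx1-cre, 0, 0 and 0 for the 3 sex differences, 2 for control sex, 3 and 0 for GRMREmx1-cre against GREmx1-cre and MREmx1-cre and 0 for non-additivity. With fry in either direction they were 11, 7 and 9, 23, 22 and 24, and 25, 27 and 28 for the 3 knockouts, 1, 1 and 2 for the sex differences, 29 and 22 for GRMREmx1-cre against the single knockouts and 15 for non-additivity. With fry in 1 direction GREmx1-cre gave 2 in females and 3 over both sexes, MREmx1-cre 10 in females, GRMREmx1-cre 14 over both sexes, the sex differences 0, 0 and 1, control sex 3 and GRMREmx1-cre against GREmx1-cre 14. Quantile normalization gave 2 in male GREmx1-cre and 1, 1 and 1 for the sex differences, and normexp 11 and 2 for those of GREmx1-cre and GRMREmx1-cre. Quantile normalization also moved the share called higher from 67.2% to 52.4% in male GREmx1-cre, 33.6% to 48.6% in female GRMREmx1-cre, 43.2% to 62.7% and 3.8% to 16.4% for the sex differences in GREmx1-cre and GRMREmx1-cre, 88.4% to 64.7% between control sexes, 43.6% to 52.1% and 29.6% to 44.6% for GRMREmx1-cre against GREmx1-cre and MREmx1-cre, and 15.9% to 33% for non-additivity. Normexp moved it to 48.8% in female GRMREmx1-cre, from 51.7% to 62% in GRMREmx1-cre over both sexes, to 30.9% for the sex difference in GREmx1-cre and to 71.1% between control sexes. In the brightest tercile alone it was 44.4%, 60.3% and 55.6% in GREmx1-cre, 57.5%, 40% and 52.8% in MREmx1-cre, 45.3%, 57.3% and 51.7% in GRMREmx1-cre, 56.5% and 27.3% for the sex differences in GREmx1-cre and GRMREmx1-cre, 64.4% between control sexes, 48.7% and 50.8% for GRMREmx1-cre against GREmx1-cre and MREmx1-cre, and 52.1% for non-additivity.

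Leaving out single arrays gave 618 to 1218, 1393 to 1567 and 1544 to 1784 for GREmx1-cre, 1527 to 2262, 3027 to 3382 and 4608 to 5074 for MREmx1-cre, and 2885 to 4198, 4929 to 5620 and 4592 to 5371 for GRMREmx1-cre. The sex differences ranged over 308 to 576, 661 to 860 and 2204 to 2565, control sex over 1258 to 1695, GRMREmx1-cre against GREmx1-cre over 5662 to 6354 and against MREmx1-cre over 2978 to 3761, and non-additivity over 2248 to 2503. Male GREmx1-cre fell to 618 without male control 3, 707 without male GREmx1-cre 3 and 795 without male GREmx1-cre 4, and male GRMREmx1-cre to 2885 without its array 2. The sex difference in GREmx1-cre gave 308 without male control 3, 341 without male control 4, 324 without female GREmx1-cre 2, 358 and 350 without female control 1 and 2, and 362 without male GREmx1-cre 1.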

Other observations

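The tests of DNA flanking Nr3c2 and of a large loss of dentate granule cells, and the shares along gene order, were chosen only after the result was seen. Single genes of signalling between neurons changed in MREmx1-cre and GRMREmx1-cre. Pdyn, the precursor of dynorphin, rose by 0.79 ± 0.10 in MREmx1-cre and 1.30 ± 0.10 in GRMREmx1-cre, while Penk, the precursor of enkephalin, fell by 0.97 ± 0.13 and 1.26 ± 0.13. Among neuropeptide and neurotrophin genes 6 of 19 rose and 2 fell in MREmx1-cre, and 7 and 3 adjusted over the list alone, at an adjusted p of 0.678 and a median of 0.06.

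Single receptor and channel genes changed as well. Grin3a, a glutamate receptor subunit, rose by 0.95 ± 0.07 in MREmx1-cre and 1.14 ± 0.08 in GRMREmx1-cre, Gabra5, a GABA receptor subunit, fell by 0.49 ± 0.06 and 0.63 ± 0.06, and Drd5, a dopamine receptor, fell by 0.65 ± 0.07 and 0.98 ± 0.07. Kcng2, a modulatory potassium channel subunit, fell by 1.31 ± 0.06 and 1.77 ± 0.07. In MREmx1-cre glutamate receptor genes rose in 5 of 22 and fell in 3, the same adjusted over the list alone, at an adjusted p of 0.872 and a median of 0.04, GABA and glycine receptor genes rose in 4 of 17 and fell in 2, the same adjusted over the list alone, at an adjusted p of 0.919 and a median of 0.04, and serotonin and monoamine receptor genes rose in 3 of 22 and fell in 3, and 3 and 4 adjusted over the list alone, at an adjusted p of 0.292 and a median of -0.08. Voltage-gated potassium channel genes rose in 6 of 25 and fell in 4 in MREmx1-cre, and 7 and 5 adjusted over the list alone, at an adjusted p of 0.678 and a median of -0.04; in GRMREmx1-cre 2 rose and 9 fell, and 3 and 9 adjusted over the list alone, at an adjusted p of 0.635, a positive median of 0.03 and a downward test.

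Genes near Nr3c2 were called in GREmx1-cre more often than others. Of the 200 nearest named genes 40% were called against 6.98% of the others, a ratio of 5.73 (Fisher's exact p = 8.48e-39, odds ratio 8.88, lower 95% bound 6.56), and along gene order the share went from 47% and 33% in the nearest 100 on each side to 16% and 22% in the next, 4% in both beyond, and then 10 of 83 on one side and 7 of 100 and 4 of 34 on the other, so the share did not fall steadily. An effect of losing the glucocorticoid receptor is argued against by GRMREmx1-cre. There the change of the called neighbours was 0.000846 of that in GREmx1-cre at the median, although 14 of them were called in the same direction. A shift of dim signals is argued against by a share of 0.1125 of called neighbours in the dimmest tercile. Of these called neighbours 80 of 80 moved the same way in both sexes. They were called on the mean of both sexes, so this agreement is no separate evidence. A candidate explanation is DNA from another strain flanking the floxed Nr3c2 allele, carried by controls and GRMREmx1-cre but not by GREmx1-cre mice, whose alleles of Nr3c2 are not given in the sources used here. Around Nr3c1 in MREmx1-cre the ratio was 1.14 (26.5% against 23.3%, Fisher's exact p = 0.275, upper 95% bound of the odds ratio 1.64). This argues against an excess there as large as around Nr3c2. A smaller excess, or one among fewer genes, stays open for that allele.

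Dentate granule cell markers were lower in MREmx1-cre at a median of -0.168, with 14 of 18 negative, and in GRMREmx1-cre at -0.41, with 12 called lower and 1 higher, where the explanations below were not tested. In MREmx1-cre a loss of granule cells as large as the falls of Dsp and Calb1 is argued against, since the other 16 markers had a median of -0.133 and a lower quartile of -0.50, while 0.5 of the change of Calb1 would be -0.70. For these markers in MREmx1-cre, a shift of dim signals as the cause of most calls is argued against by their brightness. A share of 0.1 of the called markers lay in the dimmest tercile. Of the called markers 9 of 10 had the same sign in both sexes. They were called on the mean of both sexes, so this agreement is no separate evidence. A slightly lower share of these cells and lower expression per cell cannot be told apart in MREmx1-cre, where the markers went both ways, with 8 called lower and 2 higher.

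Other ways of grouping the arrays gave the following, each with the number of groupings with as many calls as the real one. Of 35 groupings of 1 sex, 1 did for each comparison with control: in males 1290 calls in GREmx1-cre against 25 at most otherwise, 2176 in MREmx1-cre against 63 and 4399 in GRMREmx1-cre against 2257; in females 1751 against 1, 3648 against 8 and 5828 against 148. Control females and males gave 1838 against 17, also 1 of 35. With genotype exchanged within each sex, 1 of 100 did for GREmx1-cre with 1763 against 472, MREmx1-cre with 5050 against 3054, GRMREmx1-cre with 5401 against 2618, GRMREmx1-cre against GREmx1-cre with 6455 against 4140 and against MREmx1-cre with 3640 against 3297, and the non-additivity test with 2418 against 11. For each of these only the real grouping gave as many calls, which argues against chance. A share of 1 of 35 is the lowest that 35 groupings can give, so chance is not firmly excluded there. For GRMREmx1-cre against MREmx1-cre the highest other grouping came close to the real one. The slide follows the real grouping and is not excluded.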
